A study of Mus musculus with 4 samples.

How the data were processed

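The 4 libraries were made from sorted GFP-positive neural stem cells with a stranded total RNA kit and sequenced on an Illumina HiSeq as paired 100-base reads, per the labels. The RNA integrity number in the labels was 8.6 and 9.1 for control replicates 1 and 2, and 8.9 and 8.7 for TRIM8 replicates 1 and 2. The submitters' processing notes name Trimmomatic, cutadapt and TopHat2, without versions, and the genome build GRCm38. The tool that counted reads per gene, its use of strand and its annotation are not given in the sources used here. The authors deposited 1 value of RPKM per gene symbol and library, that is reads scaled by transcript length and library total, for 24440 symbols; the unit was inferred from the values, since the file headers give only a library name. The titles number 1 library of each group, which is replicate 1 here, and leave the other without a number, which is replicate 2. There were 0 columns without a sample.

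RPKM values are whole reads divided by a transcript length and a library total, and the totals were recovered from the steps between low values. Among 606 genes with a single annotated transcript, 114 gave the same totals within a relative window of 1e-05. Of 2366 genes above 0 in every library with at most 50 reads, 2004 (84.7%) then gave whole reads at a length within 25% of an annotated transcript, at a tolerance of 0.02 reads plus the rounding of the deposited digits. With the totals shifted by a few percent 2 genes (0.0845%) did. The totals were 41414620, 24602503, 29077236 and 29200750 counted reads for control replicates 1 and 2 and TRIM8 replicates 1 and 2; whether a counted read is a read or a read pair is unknown. Recovered reads of the listed genes came to about 62.5%, 60.3%, 54.9% and 61.4% of those totals, so the totals exceed the reads recovered in the listed genes. These shares are rough. For 2672 genes the recovered length was not within 25% of an annotated transcript, and for 247 no length was found. The check above covered only genes with at most 50 reads. Read numbers of single genes, and the voom, TMM and CPM alternatives that use them, carry this uncertainty. A floor of 3 reads on a transcript of 2 kb is worth 0.0362, 0.0610, 0.0516 and 0.0514 RPKM in the same order. These steps cover counting error only, since the reads carry no molecular identifiers.

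The design and the 37 gene lists were fixed before the data were examined; the design was written for counts, with limma on log2(value + 1) as the main test should the files hold normalized values. Because the deposited unit is RPKM, that test is the main result. Of the count-based tests planned first, only voom was used, on recovered reads and as an alternative. Genes with at least 0.5 RPKM in at least 2 libraries were kept (11474), values were used as deposited, and log2(RPKM + 1) was fitted in limma 3.58.1 (R 4.3.3) with the group as the only term and empirical Bayes with an intensity trend. P-values were adjusted by the Benjamini-Hochberg method at 0.05. Log2 differences are TRIM8 minus control on the log2(RPKM + 1) scale, which understates the difference of low genes; fold differences are ratios of mean RPKM. With 2 libraries against 2, an exact permutation test cannot go below 0.333. All p-values are two-sided.

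The gene lists cover neural and other cell types, the cell cycle, signalling, stress and metabolism. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists, with camera at an estimated correlation and fry beside it. Lists share some members, such as Egr1 and Cenpe. The verbs rose and fell refer to the preset test. Named genes followed a rule: Trim8, then the 8 largest differences each way past the adjusted threshold, then up to 3 such members of each list, of which there were 0, and up to 2 members with the highest mean RPKM of a list named at length. All other genes were chosen after their values were seen, including the 8 largest each way at an unadjusted p under 0.01, with a mean of at least 5 RPKM in the higher group and no overlap. Gene coordinates are those of GENCODE M21 on GRCm38. RPKM of genes that share sequence with other loci, and of overlapping or antisense genes, are uncertain because the counting is not known.

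The fit and the list test were checked on simulated data: 10 runs drawn from the real means and spreads of the TRIM8 against control comparison, with 200 genes and 1 list changed. The 200 genes were drawn only from those with a higher mean, and were shifted on the log2(RPKM + 1) scale. At the observed spread 1.2% of their 2-fold and 47.1% of their 4-fold changes were recovered, and 99.8% of their signs were right. There were 1.2 false calls per run, over 11344 genes. The changed list, whose genes were all shifted alike, was called in 10 of 10 runs. Noise was drawn independently for each gene, so these runs cannot show whether the preset list calls hold when genes vary together. At 25% of the observed spread 93.8% and 99.1% were recovered, with 8.1 false calls per run. Alternatives planned for counts were carried over to this fit: voom on recovered reads, median ratio and upper quartile scaling, no filter, a filter of 1 CPM, robust empirical Bayes, the replicate number as a block, the RNA integrity number as a covariate, and each library left out. Added after seeing the data were pseudocounts of 0.1 and 5, a filter of 1 RPKM, TMM and quantile normalization, and the block together with upper quartile scaling. The 2 libraries of a group were not duplicates of each other, since Kdm5d had 0 recovered reads in replicate 1 against 703 in replicate 2 of the controls, and 0 against 760 in TRIM8. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15.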

Results

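RNA was sequenced from neural stem cells taken from the telencephalon, the embryonic forebrain, of mouse embryos at gestation day 14 and grown with the growth factors EGF and FGF2. The cells had been infected with a retrovirus that carried FLAG-tagged murine Trim8 together with GFP, or GFP alone, and GFP-positive cells were sorted before RNA extraction. Trim8 encodes a tripartite motif protein with the RING domain of a ubiquitin ligase. The 4 libraries form 2 groups of 2, called TRIM8 and control. The series asks how the transcriptome of neural stem cells differs when Trim8 is expressed from the retrovirus. The deposited values are RPKM for 24440 gene symbols, of which 11474 reached 0.5 RPKM in at least 2 libraries and were tested. The depth recovered from the values was 41414620 counted reads in control replicate 1, 24602503 in control replicate 2, 29077236 in TRIM8 replicate 1 and 29200750 in TRIM8 replicate 2. At that depth 1 read on a transcript of 2 kb was worth between 0.0121 and 0.0203 RPKM. The labels do not say whether the libraries of a group came from separate cultures. The Y-linked gene Kdm5d had 0 recovered reads in replicate 1 of both groups, against 703 in control replicate 2 and 760 in TRIM8 replicate 2. The libraries of a group were therefore not repeats from the same pool of cells. The p-values measure only the spread between these libraries, part of which may be technical.

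The libraries separated by more than their group. Xist, the RNA of the inactive X chromosome, stood at 46.4 RPKM in control replicate 1 and 46.2 RPKM in TRIM8 replicate 1, against 20.2 RPKM in control replicate 2 and 19.2 RPKM in TRIM8 replicate 2. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were listed at 0 in both replicate 1 libraries, and Eif2s3y stood at 7.80 RPKM in control replicate 2 and 10.0 RPKM in TRIM8 replicate 2. Across genes, log2(RPKM + 1) correlated at r = 0.956 between the controls and r = 0.965 between the TRIM8 libraries. The correlation was r = 0.977 between the replicate 1 libraries of the 2 groups and r = 0.952 between the replicate 2 libraries. It was r = 0.967 between control replicate 2 and TRIM8 replicate 1 and r = 0.944 between control replicate 1 and TRIM8 replicate 2, so libraries were not always closest to those of the same group or number; genes are not independent replicates. Differences are given over all 4 libraries and also within each pair of same-numbered libraries, which were alike in Xist and Y-linked genes.

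Trim8 was higher in both TRIM8 libraries. Trim8 (ENSMUSG00000025034.9, GRCm38 chromosome 19, 46501702 to 46516848, plus strand) stood at 17.3 and 15.2 RPKM in the controls and at 42.8 and 51.9 RPKM in the TRIM8 libraries. The group means were 16.2 ± 1.45 RPKM (SD, n = 2) and 47.3 ± 6.48 RPKM (SD, n = 2), a 2.91-fold difference, and the lower TRIM8 library was 2.48-fold above the higher control. The log2 difference was 1.48 ± 0.20 (SE) over all libraries, 1.26 within the replicate 1 pair and 1.71 within the replicate 2 pair. In limma the adjusted p was 0.602 over the 11474 genes. With the replicate number as a block and upper quartile scaling, added after seeing the data, it was 0.0316 in limma and 0.00818 with voom. The exact two-sided permutation p was 0.333, the smallest that 2 libraries against 2 can give. The coding sequence in the virus is murine, so the files do not separate viral from endogenous transcripts.

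No gene passed an adjusted p of 0.05 in limma: 0 of 11474. The smallest adjusted p was 0.0965, for Gfap. At an unadjusted p under 0.05 there were 555 genes, 68 higher and 487 lower in TRIM8, where chance alone gives 574. With voom on the recovered reads the counts were 0 and 555. The replicate number as a block together with upper quartile scaling, added after seeing the data, called 10 genes in limma and 44 with voom. The median log2 difference of all tested genes was -0.09, and the upper quartile scale factor of TRIM8 replicate 1 was 0.917, the lowest of the 4 libraries. After upper quartile scaling the median was -0.03, and the unadjusted split was 170 higher and 279 lower, 37.9% higher against 12.3% before. Both TRIM8 libraries lay below both controls for 29.9% of genes and above them for 5.52%, where chance gives 16.7% each way; after upper quartile scaling the shares were 18.1% and 12.8%. Other fits called between 0 and 56 genes: the count was 56 without control replicate 1, 39 without control replicate 2 and 0 without either TRIM8 library. On simulated data with the observed spread, 47.1% of genes changed 4-fold and 1.2% of genes changed 2-fold were recovered. Only genes with a higher mean were changed there, so these shares do not cover low genes.

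Among the 8 largest separated differences in each direction, chosen after their values were seen at an unadjusted p under 0.01, were the astrocyte genes Gfap and Agt. Gfap (GRCm38 chromosome 11, 102887336 to 102900912), the intermediate filament protein of astrocytes, was 6.48-fold lower in TRIM8, with 45.6 ± 0.514 RPKM (SD, n = 2) in controls and 7.03 ± 0.915 RPKM (SD, n = 2) in TRIM8. Agt, which encodes angiotensinogen, was 3.90-fold lower, at 23.9 and 29.5 RPKM in controls and 9.03 and 4.66 RPKM in TRIM8. Lars2, the mitochondrial leucyl-tRNA synthetase, stood at 87.9 and 337 RPKM in controls and at 6.50 and 7.07 RPKM in TRIM8, a 31.3-fold difference of means, with a control SD of 82.8% of the control mean. Csdc2 was 3.41-fold lower, Padi2 9.72-fold, Entpd2 6.25-fold, Psd2 4.54-fold and Ppp1r3c 4.04-fold. In the other direction, beside Trim8 itself, Rgs16, a regulator of G protein signalling, was 4.56-fold higher, at 1.99 ± 1.29 RPKM (SD, n = 2) against 9.09 ± 0.0169 RPKM (SD, n = 2). Tnfaip6 was 3.47-fold higher, Fas 3.38-fold, Arl4d 2.98-fold, Id3 2.33-fold, Ccnd1 2.26-fold and Hsp90b1 1.95-fold. The limma adjusted p of these genes lay between 0.0965 and 0.870 in the fit of the group alone on the values as deposited. Without control replicate 1, Gfap, Agt, Lars2, Csdc2, Padi2, Rgs16 and Arl4d passed an adjusted p of 0.05, and without control replicate 2, Gfap, Agt, Lars2, Csdc2, Padi2, Entpd2, Psd2 and Rgs16 did; none of the genes in this paragraph passed without either TRIM8 library. Because these genes were chosen without overlap of the libraries, the choice itself fixed their directions within both pairs. The directions also held after upper quartile scaling, whose factors lay only between 0.917 and 1.05. Without control replicate 1 the difference was 5.63-fold for Padi2, 49.6-fold for Lars2, 8.42-fold for Rgs16 and 4.48-fold for Arl4d, and without control replicate 2 it was 13.0-fold for Lars2. Without TRIM8 replicate 1 it was 7.63-fold for Psd2 and 9.02-fold for Ppp1r3c, and without TRIM8 replicate 2 it was 2.16-fold for Fas. The log2 difference of Ppp1r3c moved from -2.06 to -1.30 without TRIM8 replicate 2, and that of Id3 from 1.27 to 0.82 without control replicate 2.

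**Figure D1:**
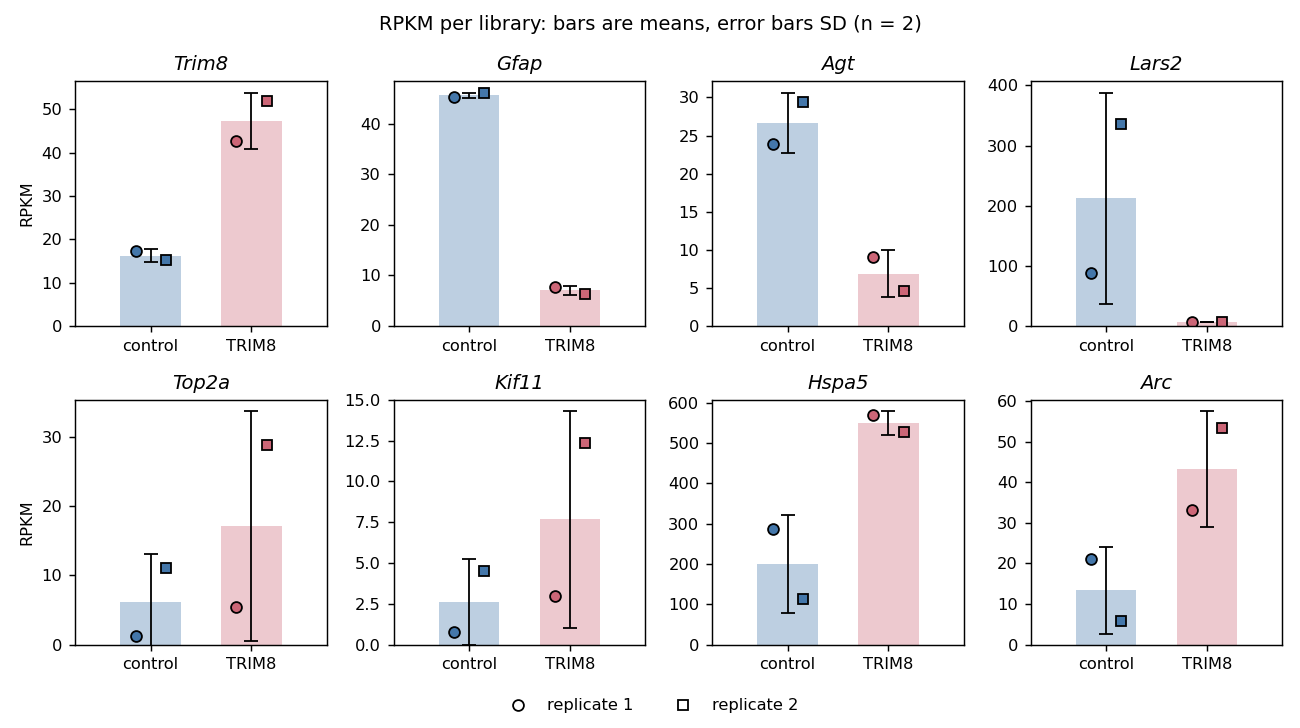
RPKM (vertical axes, linear, from 0) of 8 genes in the control and TRIM8 libraries; bars are group means, error bars the SD (n = 2, not drawn below 0), circles replicate 1 and squares replicate 2. Both TRIM8 libraries lie above both controls for Trim8, Hspa5 and Arc and below them for Gfap, Agt and Lars2, while Top2a and Kif11 overlap, with replicate 2 above replicate 1 in each group.

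Of the 37 gene lists, 30 had at least 5 tested members, and 18 passed an adjusted p of 0.05 in camera with a preset correlation of 0.01, 14 higher and 4 lower. Split by title number instead, the same libraries gave 14 lists past this test. Control replicate 2 with TRIM8 replicate 1, set against the other libraries, gave 10. The preset test thus also calls many lists when the libraries are grouped otherwise. With the correlation estimated from the data, 0 lists passed (smallest adjusted p = 0.468), and 0 passed in fry, either one-way (smallest adjusted p = 0.441) or mixed (smallest adjusted p = 0.275). In the fit of the group alone no list member passed over all genes; adjusted over the list alone, 11 members did. The 6 lists whose median and camera direction differed in sign were all among those that did not pass.

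Genes of astrocytes and of the oligodendrocyte lineage fell. Of 17 astrocyte genes, 15 were lower in TRIM8 and 11 were lower without overlap of the libraries, against 29.9% of all tested genes. The median log2 difference was -0.63 over all libraries, -0.39 within the replicate 1 pair and -0.88 within the replicate 2 pair (camera adjusted p = 1.58e-08, adjusted p = 0.468 with an estimated correlation). Adjusted over the list alone, 5 passed: Gfap, Agt, Clu, Gja1 and Aqp4. Gja1, the gap junction protein connexin 43, stood at 76.3 and 61.9 RPKM in controls and 34.5 and 22.5 RPKM in TRIM8, and the water channel gene Aqp4 at 26.1 and 27.0 against 17.9 and 10.9 RPKM. Of the astrocyte genes with the highest RPKM, Cst3 had a log2 difference of -0.71 and was lower without overlap, whereas Apoe, at -0.88, overlapped and differed by 0.03 in the replicate 1 pair and -1.78 in the replicate 2 pair. The Apoe difference was -0.39 without TRIM8 replicate 2, -0.46 without control replicate 2 and -1.37 without TRIM8 replicate 1. Aldh1l1 and Acsbg1 had positive differences of 0.40 and 0.80, which were -0.35 and -0.28 without control replicate 1 and 1.14 and 1.88 without control replicate 2; Aldh1l1 was at 0.20 without TRIM8 replicate 1 and Acsbg1 at 0.43 without TRIM8 replicate 2. All 16 tested oligodendrocyte lineage genes were lower, with a median of -0.50 (camera adjusted p = 8.15e-05, adjusted p = 0.486 with an estimated correlation). Sox10, a transcription factor of that lineage, was 2.21-fold lower, Gpr17, a receptor of immature oligodendrocytes, 1.97-fold lower and Olig2 1.36-fold lower (log2 difference -0.43, and -0.28 without control replicate 1). This median was -0.88 within the replicate 1 pair and -0.25 within the replicate 2 pair, and the call ended without TRIM8 replicate 1 (median -0.22, adjusted p = 0.0896); without TRIM8 replicate 2 the median was -0.88. Astrocyte medians ran from -0.80 to -0.48 with 1 library left out, and the call held each time.

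The list of neural stem cells and radial glia did not pass (camera adjusted p = 0.902), with 6 genes higher and 16 lower. Without overlap of the libraries, 2 members were higher and 7 lower. Among the higher, Nes, the intermediate filament protein nestin, stood at 19.9 and 29.7 RPKM in controls and 36.2 and 55.5 RPKM in TRIM8. Among the lower, Msi1 stood at 22.1 and 16.5 RPKM in controls and 12.8 and 12.5 RPKM in TRIM8. Fabp7 and Vim, the members with the highest RPKM, had log2 differences of 0.69 and 0.60 and overlapped between the groups. The pairs gave 1.17 and 0.21 for Fabp7 and 0.87 and 0.34 for Vim. Without control replicate 1 the differences were 0.01 and 0.09, without control replicate 2 they were 1.36 and 1.12, and without TRIM8 replicate 2 that of Vim was 0.35. The neuron list did not pass either on the values as deposited (adjusted p = 0.101, adjusted p = 0.912 with an estimated correlation), with 12 of 14 genes lower and a median of -0.37; the pairs gave -0.92 and 0.10. It did pass as lower in 10 other settings, among them upper quartile scaling (median -0.31, adjusted p = 0.0217) and the fits without control replicate 2 (-0.71, adjusted p = 1.16e-06) and without TRIM8 replicate 2 (-0.60, adjusted p = 0.000810), and the median was -0.02 without control replicate 1 and -0.23 without TRIM8 replicate 1. Mapt, which encodes tau, was the only neuronal member past the threshold adjusted over the list alone, at 13.3 ± 0.842 RPKM against 7.01 ± 0.922 RPKM (SD, n = 2). Synaptic protein genes fell, with 19 of 21 lower and a median of -0.23 (adjusted p = 0.0478, adjusted p = 0.879 with an estimated correlation), and that call ended without control replicate 1, TRIM8 replicate 1 or TRIM8 replicate 2 (adjusted p = 0.917, 0.151 and 0.0807). It also ended with a filter of 1 CPM (adjusted p = 0.0602), a filter of 1 RPKM (adjusted p = 0.0527) and a pseudocount of 5 (adjusted p = 0.0956). Their median was -0.04 without control replicate 1 and -0.40 without control replicate 2.

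Genes of mitosis rose. All 22 genes of the G2 and M phase list were higher in TRIM8 within both pairs, with a median log2 difference of 0.90, 0.83 in the replicate 1 pair and 1.01 in the replicate 2 pair (camera adjusted p = 9.23e-12, adjusted p = 0.486 with an estimated correlation). All 12 tested mitotic kinesins were also higher in both pairs, with a median of 0.80 (adjusted p = 9.51e-08, adjusted p = 0.486 with an estimated correlation). Top2a, which encodes topoisomerase II alpha, stood at 1.26 RPKM in control replicate 1 and 5.41 RPKM in TRIM8 replicate 1, and at 11.1 and 28.9 RPKM in the replicate 2 libraries. Ccnb1, the mitotic cyclin B1, stood at 0.365 and 3.40 RPKM in the replicate 1 libraries and 7.16 and 20.3 RPKM in the replicate 2 libraries. Kif11, a kinesin of the mitotic spindle, stood at 0.747 and 2.98 RPKM and at 4.50 and 12.4 RPKM. No member of the G2 and M phase list separated the groups over all 4 libraries, and these genes were also higher in replicate 2 than in replicate 1, by a median log2 difference of 1.52. The median was 0.20 without control replicate 1 and 0.12 without TRIM8 replicate 2, and was 1.70 without control replicate 2 and 1.67 without TRIM8 replicate 1. For the kinesins these values were 0.18, 0.07, 1.34 and 1.51. S phase genes rose, with 18 of 20 higher and a median of 0.33 (adjusted p = 3.79e-05, adjusted p = 0.679 with an estimated correlation). The S phase median was -0.04 in the replicate 1 pair and 0.77 in the replicate 2 pair, and the call ended without control replicate 1 (median 0.06, adjusted p = 0.215) or TRIM8 replicate 2 (-0.27, adjusted p = 0.0796); it was 0.65 without control replicate 2 and 1.02 without TRIM8 replicate 1.

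Immediate early genes, which are transcribed within minutes of a stimulus, rose, with 15 of 15 higher and a median of 1.18 (camera adjusted p = 4.97e-09, adjusted p = 0.486 with an estimated correlation). The median was 0.09 in the replicate 1 pair and 1.60 in the replicate 2 pair, and without control replicate 2 it was -0.04 and the call ended (adjusted p = 0.686). It was 2.29 without control replicate 1 and 0.48 without TRIM8 replicate 1. Arc stood at 21.0 and 5.85 RPKM in controls and 33.2 and 53.4 RPKM in TRIM8, and Egr1 at 330 and 67.9 RPKM against 333 and 190 RPKM. Feedback targets of EGF and FGF signalling rose, with 13 of 14 higher and a median of 0.64 (adjusted p = 2.98e-08, adjusted p = 0.468 with an estimated correlation). Their median was -0.08 in the replicate 1 pair and 1.36 in the replicate 2 pair, and it was 0.13 without control replicate 2, 0.39 without TRIM8 replicate 2 and 1.22 without control replicate 1. Spry2 stood at 111 and 33.5 RPKM in controls and 95.6 and 86.4 RPKM in TRIM8, whereas Dusp6, an ERK phosphatase gene, was higher in both TRIM8 libraries, at 22.8 and 31.0 RPKM against 16.7 and 14.5 RPKM. BMP and TGF-beta targets rose, with 7 of 8 higher and a median of 0.64 (adjusted p = 4.52e-06, adjusted p = 0.468 with an estimated correlation), 0.06 in the replicate 1 pair and 1.44 in the replicate 2 pair. Their median was 0.11 without control replicate 2, 0.37 without TRIM8 replicate 2 and 1.34 without control replicate 1. Adjusted over the list alone, Id1, Id3 and Ctgf passed; Id3, an inhibitor of differentiation, stood at 70.7 and 37.1 RPKM in controls and 123 and 128 RPKM in TRIM8.

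**Figure D2:**
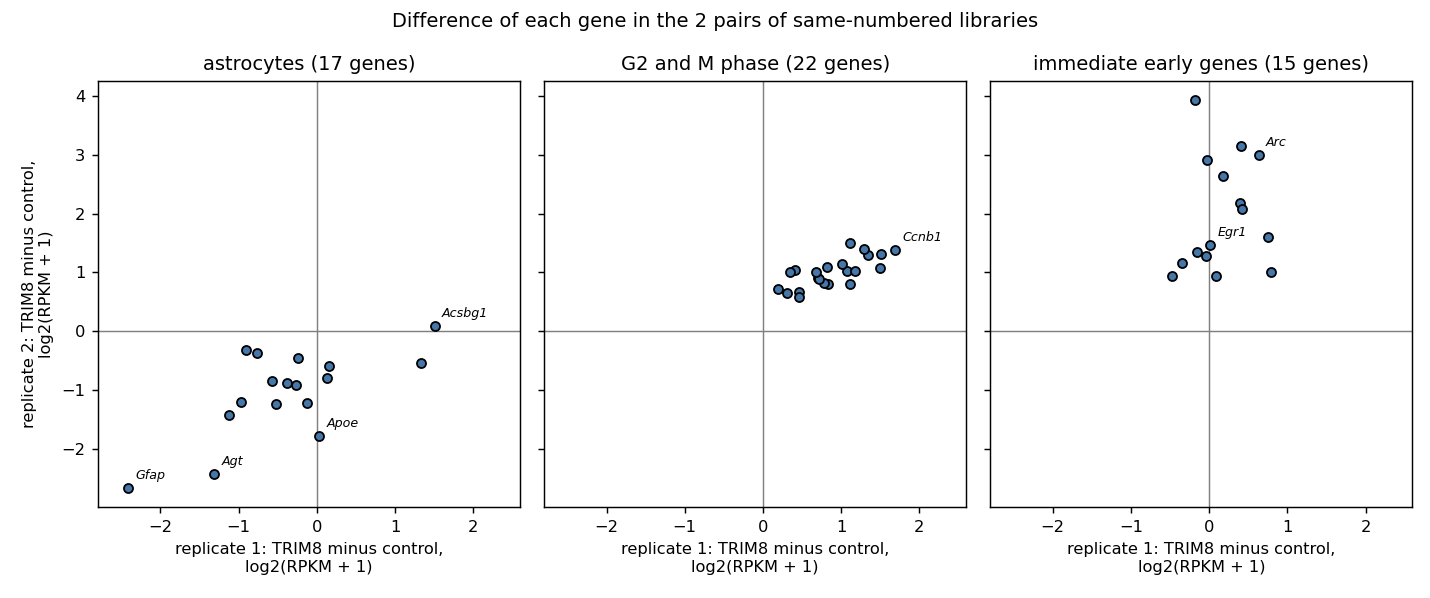
Log2 difference of each tested gene of 3 lists, TRIM8 minus control on log2(RPKM + 1), in the replicate 1 pair (horizontal axis) and the replicate 2 pair (vertical axis), 1 point per gene. All 22 G2 and M phase genes lie above 0 on both axes, 12 of the 17 astrocyte genes lie below 0 on both, and the immediate early genes lie above 0 on the vertical axis with a horizontal median of 0.09.

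Genes of endoplasmic reticulum stress and the amino acid response rose as a list, with 10 of 16 higher and a median of 0.38 (camera adjusted p = 0.000115, adjusted p = 0.468 with an estimated correlation), 0.01 in the replicate 1 pair and 0.69 in the replicate 2 pair. The median was 0.20 without control replicate 2 and -0.08 without TRIM8 replicate 2. Among its chaperones, Hspa5 stood at 285 and 113 RPKM in controls and 570 and 528 RPKM in TRIM8, and Hsp90b1 at 63.8 and 63.9 against 111 and 139 RPKM. Phgdh, an enzyme of serine synthesis, was 1.70-fold lower. Heat shock genes rose by little, with 12 of 12 higher and a median of 0.22 (adjusted p = 4.52e-06, adjusted p = 0.468 with an estimated correlation), 0.08 and 0.27 within the pairs. This median was 0.04 without TRIM8 replicate 2, 0.35 without control replicate 2 and 0.45 without TRIM8 replicate 1. Cholesterol synthesis genes rose, with 16 of 18 higher and a median of 0.27 (adjusted p = 4.52e-06, adjusted p = 0.554 with an estimated correlation); the pairs gave -0.12 and 0.58, and the call ended without TRIM8 replicate 2 (median -0.12, adjusted p = 0.980). It was 0.68 without TRIM8 replicate 1. Insig1, a sterol-regulated protein of the endoplasmic reticulum, had a log2 difference of 0.80, 0.14 in the replicate 1 pair and 1.46 in the replicate 2 pair; it was 0.26 without control replicate 2 and 1.35 without control replicate 1.

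The p53 targets (13 of 18 higher, median 0.18, adjusted p = 8.15e-05), mesenchymal genes of glioma (9 of 10, 0.43, adjusted p = 0.000850), Wnt targets (5 of 7, 0.40, adjusted p = 0.000998), NF-kB targets (6 of 9, 0.32, adjusted p = 0.00116) and interferon-stimulated genes (6 of 9, 0.09, adjusted p = 0.0345) also passed as higher. Each of these calls was lost with an estimated correlation (adjusted p = 0.468 for the first 4 and 0.505 for the last). The p53 median ran from -0.07 without TRIM8 replicate 2 to 0.45 without TRIM8 replicate 1, with -0.01 without control replicate 1 and 0.29 without control replicate 2. The mesenchymal call ended without control replicate 2 (0.28, adjusted p = 0.256) or TRIM8 replicate 2 (0.01, adjusted p = 0.113), with 1.02 without TRIM8 replicate 1. The Wnt call ended without TRIM8 replicate 1 (adjusted p = 0.0899), and the NF-kB call without control replicate 2 (-0.01, adjusted p = 0.0726) or TRIM8 replicate 1 (0.21, adjusted p = 0.20). Without control replicate 2 the Wnt median was -0.00, and without TRIM8 replicate 2 the NF-kB median was 0.08. Ccnd1, which encodes cyclin D1, was the only Wnt member past the threshold adjusted over the list alone, at 14.5 and 15.4 RPKM against 26.4 and 41.3 RPKM. Other members of the TRIM family fell, with 21 of 25 lower and a median of -0.24 (adjusted p = 0.0323, adjusted p = 0.468 with an estimated correlation), -0.29 and -0.27 within the pairs. Trim2 was 1.79-fold lower and Trim35 1.22-fold lower. The TRIM family call ended without control replicate 1 (adjusted p = 0.364) or TRIM8 replicate 2 (adjusted p = 0.0505). The interferon call ended under upper quartile scaling (adjusted p = 0.0624), median ratio scaling (0.0735), TMM (0.0712), no filter (0.0881) and a filter of 1 RPKM (0.0887). It also ended without control replicate 1 (0.03, adjusted p = 0.617), TRIM8 replicate 1 (0.12, adjusted p = 0.0896) or TRIM8 replicate 2 (0.05, adjusted p = 0.0796), with 0.24 without control replicate 2.

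**Figure D3:**
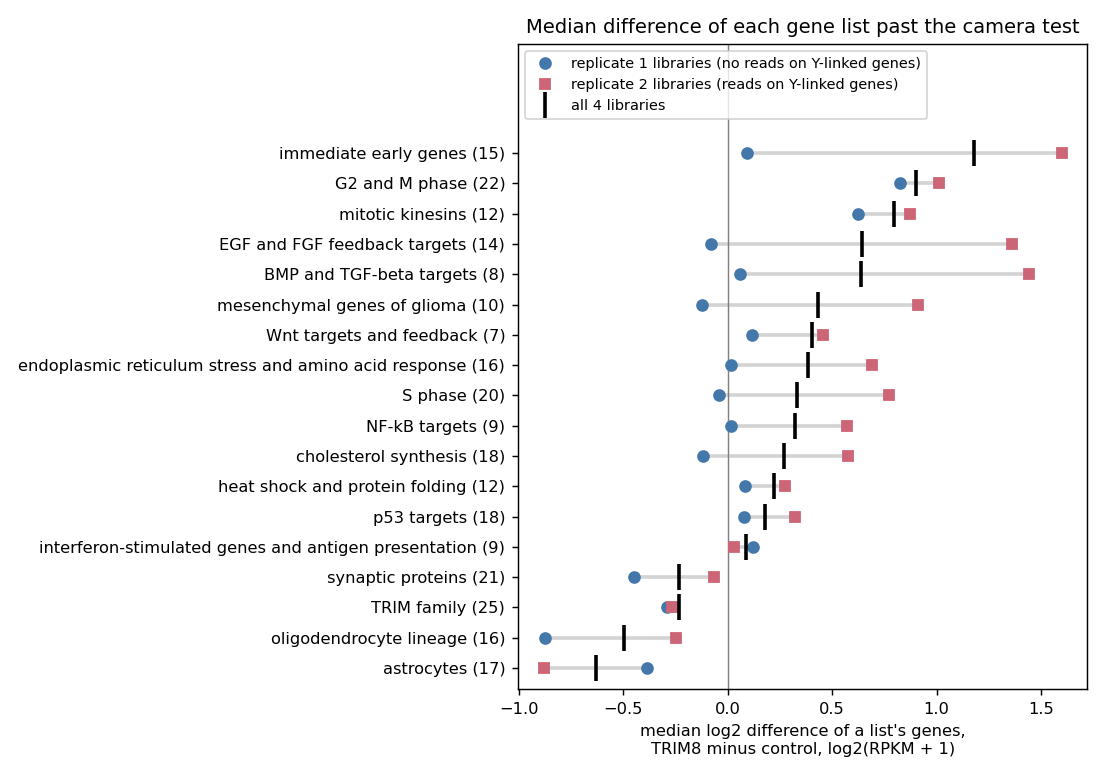
Median log2 difference, TRIM8 minus control on log2(RPKM + 1), of the 18 gene lists past camera with the preset correlation (tested genes in brackets); circles are the replicate 1 pair, squares the replicate 2 pair and black bars all 4 libraries. G2 and M phase genes (0.83 and 1.01) and astrocyte genes (-0.39 and -0.88) lie on 1 side of 0 in both pairs. So do immediate early genes, which span 0.09 to 1.60, whereas EGF and FGF feedback targets (-0.08 and 1.36) lie on both sides.

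The remaining tested lists did not pass. The JAK-STAT list had 9 genes higher and 12 lower (camera adjusted p = 0.662). Stat3, picked from the 9 higher genes, stood at 35.7 and 26.4 RPKM in controls and 41.4 and 59.6 RPKM in TRIM8. The glioma driver list had 8 higher and 16 lower (camera adjusted p = 0.675) and the Notch list 4 higher and 12 lower (camera adjusted p = 0.990). Hey1, a Notch effector among the 4 higher genes, stood at 37.0 and 20.1 RPKM in controls and 45.1 and 90.5 RPKM in TRIM8. Its log2 difference was 0.28 in the replicate 1 pair and 2.12 in the replicate 2 pair. Nrarp, among the 12 lower genes, stood at 14.3 and 17.8 RPKM in controls and 10.7 and 11.6 RPKM in TRIM8. Voltage-gated ion channels, Hedgehog, glutamate and GABA receptors, replication-dependent histones, ribosomal proteins, intermediate progenitors, and hypoxia and glycolysis gave camera adjusted p between 0.578 and 0.902. With 1 library left out, the lists of histones, ribosomal proteins, intermediate progenitors, and hypoxia and glycolysis passed in some fits, each in opposite directions depending on the library.

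Few markers of cells outside the neural lineage were tested. Of the 16 microglia genes 1 was tested and the others stayed at or below 0.0618 RPKM. None of the 12 endothelial and 10 erythroid genes was tested, with highest values of 0.396 and 0.132 RPKM. Pericyte and fibroblast genes had 3 tested members, of which Pdgfrb stood at 5.59 and 1.52 RPKM in controls and 0.629 and 0.177 RPKM in TRIM8. Among the untested pericyte and fibroblast genes Acta2, an actin of smooth muscle, had the highest value, 2.52 RPKM in TRIM8 replicate 2, and stayed between 0.0845 and 0.284 RPKM in the other 3 libraries. The GABAergic lineage had 3 tested members and the ependymal list 4, and the symbols of the mitochondrially encoded genes were not analysed here.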

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

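The pseudocounts of 0.1 and 5 for gene calls, the filter of 1 RPKM, TMM, quantile normalization and the replicate block with upper quartile scaling were chosen after seeing the data; the other alternatives were planned. The planned count-based tests other than voom on recovered reads were not run, because the values are RPKM. Scaling by library totals alone equals the values as deposited. No gene passed an adjusted p of 0.05 in limma on the values as deposited (0, with 555 at an unadjusted p under 0.05). Robust empirical Bayes called 1 gene, Gfap (adjusted p = 0.0397), and leaving out 1 library gave 0 to 56 genes. Where 1 library was left out, the lone library of its group was assumed to vary like the other group, and the cause of these changes was not tested.

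Same-numbered libraries deviated together (correlation of deviations across genes 0.232), but only 2 pairs exist and the labels do not say what the number marks. The replicate block called 0 genes, with 833 at an unadjusted p under 0.05. With upper quartile scaling as well it called 10 genes in limma, 3 higher and 7 lower, and 44 with voom, and Trim8 passed in both (log2 difference 1.56, adjusted p = 0.0316, and 1.62, adjusted p = 0.00818). So did Gfap, Lars2, Padi2, Entpd2, Psd2, Rgs16 and Csdc2 (adjusted p = 0.00485 to 0.0425 in limma). Of the mitotic genes, Ccnb1 passed in limma (adjusted p = 0.0481) but not with voom, and Top2a, Kif11, Mki67 and Nusap1 passed with voom (adjusted p = 0.0190, 0.0285, 0.0314 and 0.0371) but not in limma. Agt, Gja1, Tnfaip6, Id3, Ccnd1, Hspa5, Pdgfrb and Rn45s also passed with voom alone (adjusted p = 0.00738 to 0.0373). These 2 fits ended the interferon call (adjusted p = 0.0688 and 0.0758). Over the other settings on all 4 libraries the adjusted p of Trim8 lay between 0.140 and 0.897, and with 1 library left out it was at least 0.0607.

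Of 18 lists past camera with the preset correlation, 0 passed with an estimated correlation, 0 in fry and 0 in mixed fry. 6 kept their call and direction in every preset fit: G2 and M phase, mitotic kinesins, astrocytes, EGF and FGF feedback targets, BMP and TGF-beta targets, and heat shock genes. A kept call did not mean equal differences in the pairs. In that order the medians were 0.83, 0.62, -0.39, -0.08, 0.06 and 0.08 in the replicate 1 pair. In the replicate 2 pair they were 1.01, 0.87, -0.88, 1.36, 1.44 and 0.27. All of the other 12 changed with 1 library left out. List medians then ran from -0.042 to 2.29 for immediate early genes, -0.12 to 0.68 for cholesterol synthesis, -0.27 to 1.02 for S phase, -0.066 to 0.45 for p53 targets, -0.078 to 0.56 for endoplasmic reticulum stress, -0.0036 to 0.52 for Wnt targets, -0.0051 to 0.42 for NF-kB targets and -0.40 to -0.043 for synaptic proteins. The interferon median was -0.0022 with no filter. Of 12 tested lists that did not pass, 5 passed in at least 1 setting, among them neurons as lower under upper quartile scaling (adjusted p = 0.0217).

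None of the 55 named genes was called in the main fit, so keeping the side of the threshold meant only staying uncalled. Robust empirical Bayes and the replicate block cannot change a log2 difference, so no direction could reverse there. Over these genes, 796 of 825 values under other settings kept their direction and side of the threshold, and 29 gained a call. With 1 library left out 194 of 218 did, 19 gained a call and 5 reversed. Log2 differences ran from -0.39 to 1.87 for Egr1, -0.28 to 1.41 for Spry2, -0.44 to 1.05 for Pcna, -0.35 to 1.14 for Aldh1l1 and -0.28 to 1.88 for Acsbg1. The mean within-group correlation across genes was 0.961, and 0.980 over every gene with a read or 0.967 with a pseudocount of 5. Depth limits low genes: 3 reads on a transcript of 2 kb are worth 0.0362 to 0.0610 RPKM.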

Other observations

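All tests below were chosen after the result was seen, except that on the other mitochondrial aminoacyl-tRNA synthetases. Rn45s, the ribosomal RNA precursor, stood at 859 and 1578 RPKM in controls and 304 and 510 RPKM in TRIM8. Rpph1, the RNA of ribonuclease P, stood at 11113 and 11751 RPKM against 6188 and 5921 RPKM, and Rmrp, the RNA of ribonuclease MRP, at 5856 and 7671 RPKM against 4244 and 4605 RPKM. These 3 genes were picked after their values were seen, and none passed an adjusted p of 0.05 in limma on the values as deposited. Rn45s passed in 1 alternative, the replicate block with upper quartile scaling and voom (log2 difference -1.48, adjusted p = 0.0170).

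Lars2 was lower in both TRIM8 libraries, with a log2 difference of -4.48 ± 0.58 (SE). Library scale is excluded as the whole cause, since the difference was -4.40 after upper quartile scaling. Carry-over is excluded only in a fixed proportion to Rn45s, since the lowest control ratio of Lars2 to Rn45s was 4.80 times the highest TRIM8 ratio. That ratio also differed between the controls, at 0.102 and 0.213, and carry-over in a varying proportion was not tested. A fall shared by the 16 other mitochondrial aminoacyl-tRNA synthetase genes is excluded, since their median was -0.067 (range -0.55 to 0.08). Those genes stood between 0.266 and 12.8 RPKM over the libraries. Lars2 in TRIM8, at 6.50 and 7.07 RPKM, lay within that range, while the controls, at 87.9 and 337 RPKM, lay far above it. An effect of Trim8 on Lars2 may remain, but the exact permutation p of 0.333 is the smallest this design allows. Sequence shared with ribosomal RNA was not analysed here, so the source of the high control values stays open.

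The 33 genes of the G2 and M phase and mitotic kinesin lists were higher in TRIM8 within both pairs, with a median of 0.84. Library scale is excluded as the whole cause (0.86 after upper quartile scaling). Each group held a library with and a library without reads on Y-linked genes, so that difference was balanced between the groups by design. The within-pair medians of 0.72 and 1.01 could therefore not weigh it as a cause. They show only that the genes were higher in both pairs. A difference in growth between cultures could account for it as well as Trim8 could. The split by title number, which also parts libraries with and without reads on Y-linked genes, gave a median of 1.40. Control replicate 2 with TRIM8 replicate 1, set against the other libraries, gave -0.08. Neither split isolates growth, so these explanations cannot be told apart with 4 libraries.

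Astrocyte genes were lower in TRIM8, with a median of -0.63 that was -0.57 after upper quartile scaling, which excludes library scale as the whole cause. The within-pair median nearer to 0 was -0.39, and 12 of the 17 genes were lower in both pairs. This could not weigh the difference between libraries with and without reads on Y-linked genes, which the design balances between the groups. Fewer astrocyte-like cells among the sorted cells may still account for part: the SD of the members' differences was 2.87 times their median SE, but these genes are not specific to astrocytes in such cultures, so this stays open.

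The 4 libraries can be split into 2 groups of 2 in 3 ways, too few for a share under 0.05. The real split gave 555 genes at an unadjusted p under 0.05 and the highest other 736, the split by title number, so 2 of the 3 splits gave as many genes. For gene lists past camera the real split gave 18, the split by title number 14 and the remaining split 10, so 1 of the 3 gave as many.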
